A study of Mus musculus with 2 samples.

How the data were processed

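Single-cell RNA profiles of mouse islets were measured in 2 libraries, 1 of flox/flox mice and 1 labelled BcBKO. Islets were digested to single cells with TrypLE, a trypsin substitute, and captured in droplets, where each RNA molecule receives a barcode of its cell and a unique molecular identifier (UMI) at its 3′ end. For each library the authors deposited a matrix of counts, whole numbers of UMIs per gene and barcode without normalisation, with 28692 genes. Per the labels, reads were processed with Cell Ranger 3.1.0 and Seurat 4.0.0 on mm10, while the header of the deposited count matrix names version 6.1.2 of the counting software; which of them made the counts could not be settled. The gene annotation that the authors used is not stated; positions were taken from GENCODE M21 (GRCm38), which holds 28339 of the 28692 gene identifiers.

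Both libraries were used in full. Barcodes with fewer than 500 genes or 1000 UMIs (1625 of 9438 for flox/flox and 1931 of 10775 for the library labelled BcBKO) or with over 20% of UMIs from mitochondrial genes (582 and 703) were removed, which left 7568 and 8504. Doublets were called in each library with Scrublet, as included in scanpy 1.11.5, at an assumed rate of 8% and with its automatic threshold, and 182 (2.40%) and 218 (2.56%) were removed. Doublets of like cells are not found by this method. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes (chosen per library), 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1, with both libraries together, no batch correction and seed 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 were used, with edgeR 4.0.16 in R 4.3.3 for TMM factors.

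The 29 clusters were named from fixed lists of marker genes, by the highest mean standardised marker level. A cluster stayed unnamed if fewer than 3 markers were detected, if its markers averaged under 10% of their level in the best cluster, if it was endocrine with several hormones (insulin genes from 250000 CPM, Gcg or Sst from 15000 CPM, Ppy from 60000 CPM), if its 10 leading genes held more markers of another class, if it was endocrine and had at least 2 proliferation genes among its leading genes, or if its UMIs per cell were low and none of its markers was among its leading genes. Low meant under the library median divided by 2. These thresholds were set after the clusters had been seen, after other versions (a summed marker score, hormone thresholds relative to each cluster and a divisor of 3) gave unstable or empty names. In all, 10 clusters stayed unnamed. Clusters with leading genes of another class held 1.52% and 1.69% of kept cells, and the other reasons are given with the class shares. Names end in "-like" because they rest on markers alone.

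For each class with at least 50 cells per library, UMIs were summed over cells and divided by the class total to give CPM. Beta-like cells had 113336622 UMIs in the flox/flox library and 106536217 in the library labelled BcBKO. The log2 ratio is that of CPM plus a pseudocount of 1 CPM, which understates the difference of low genes. Intervals for CPM are exact Poisson intervals, those for log2 ratios and list medians come from 2000 Poisson draws, those for CPM ratios of Smarcd3 are exact conditional intervals, and those for shares are exact binomial (Clopper-Pearson) intervals, all at 95%. Limits for a count of 0 are 3 counts of the total. With 1 library per group none of them covers differences between mice or between preparations.

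Comparisons, marker and gene lists, matching rule, minimum levels and the rule for naming genes were chosen before the data were examined. Genes were compared at 20 CPM or more in either library in beta-like cells and at 50 CPM in alpha-like and delta-like cells. The named genes are the 12 highest and the 12 lowest log2 ratios in beta-like cells and the 5 highest and lowest in alpha-like and delta-like cells, the extremes of each fixed list, and a fixed set of beta-cell genes; not every gene that the rule takes is given in the text. Mitochondrial, ribosomal protein and sex-linked genes, unnamed gene models, acinar markers and the other islet hormones were not eligible for naming by size. Nor was a gene whose CPM in another class was over 5 times its own, both taken in the library where its own was higher, since free RNA from that class could give its UMIs. Eligible genes numbered 2259 of 2894 in beta-like cells. Each list median was placed among 10000 random lists of as many genes drawn from 20 bins of level. The fixed symbols Ero1b, Pc and Amy2b were absent from the files.

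The procedure was tested on simulated data, with counts drawn from the measured levels and known differences put in. The intervals covered the true value for 94.5% of 2894 genes, the sign was recovered for 100% of 100 genes at 2-fold and of 100 genes at 1.5-fold, and 0 of 2694 unchanged genes passed 1.5-fold. Of 200 random lists 2.00% lay outside the central 95%. This simulation holds counting error alone.

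Alternatives were a stricter cell filter (1000 genes, 2000 UMIs, 10% mitochondrial) and none, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered on its own, TMM scaling, totals without hormones and mitochondrial genes, equal weight per cell, beta-like cells thinned to 26000 UMIs, beta-like cells with at most 1% of UMIs from other hormones and acinar markers (17 and 66 cells left out), pseudocounts of 0.1 and 5 CPM, and no minimum or 100 CPM as the minimum level. One alternative was chosen after seeing the data: of the 3 beta-like clusters, 1 held 41 cells of the flox/flox library and 334 of the library labelled BcBKO, and it was left out. Alternatives were run for beta-like cells alone, so the lists of alpha-like and delta-like cells were not checked under other scalings. A list of 12 glucocorticoid-induced genes and a test of genes within 10 Mb of Smarcd3 were also chosen after seeing the data, the latter after windows of that size along the genome had been looked at. RNA velocity, splicing and reads were not analysed here.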

Results

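The series concerns BAF60C, a subunit of the BAF chromatin-remodelling complexes encoded by Smarcd3, and its title places the question in type 2 diabetes. Pancreatic islets of flox/flox mice were compared with islets of mice labelled BcBKO, which the series describes as a beta-cell-specific ablation and associates with Pdx1-cre, a Cre recombinase driven by the promoter of a transcription factor of the embryonic pancreas and of adult beta cells. The ablated gene is read here from the title as Smarcd3. Each group was 1 droplet library of single cells, made with a 3′ tag-counting kit from islets pooled from at least 3 mice per group. The flox/flox library had 9438 deposited barcodes and 167670996 UMIs (counted RNA molecules), with a median of 6670.5 UMIs per barcode. The library labelled BcBKO had 10775 barcodes and 178647270 UMIs, with a median of 6923. The labels state that about 16000 cells were loaded and about 10000 captured per library. After filtering, 7386 and 8286 cells remained, with medians of 11768.5 and 12346 UMIs. Because each group is a single pooled library, no gene or cell class has replicates, no test between groups was possible, and every interval given is a 95% interval that covers counting error only.

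Smarcd3 was not lower in beta-like cells of the library labelled BcBKO. The gene (ENSMUSG00000028949; mm10 chromosome 5, 24590818 to 24624411, minus strand) had 33 UMIs in beta-like cells of the flox/flox library, or 0.291 CPM (its UMIs over all UMIs of the class, times 1000000; interval 0.200 to 0.409). It had 58 UMIs in the library labelled BcBKO, or 0.544 CPM (0.413 to 0.704), and the ratio was 1.87 (1.20 to 2.96). In alpha-like cells the counts were 8 and 20 UMIs, a ratio of 2.01 (0.848 to 5.28), and in delta-like cells they were 1 and 2. Among classes of at least 50 cells per library, Smarcd3 had its highest CPM in mural-like cells. There it was lower in the library labelled BcBKO, at 19.8 against 26.8 CPM (ratio 0.736, 0.566 to 0.952). In duct-like cells, a cluster whose name is uncertain because its 10 leading genes hold the duct markers Krt19 and Spp1 but also Fabp1, Fabp2, Rbp2, Sct and Spink4, genes known from the intestine, it was 16.76 against 16.03 CPM (ratio 1.05, 0.632 to 1.75). Smarcd1 and Smarcd2, which encode the alternative BAF60A and BAF60B subunits, had log2 ratios of −0.08 and 0.10 in beta-like cells, with levels of 8.14 and 8.33 CPM in the flox/flox library. The direction therefore goes against the genotype label, and for that reason the library is called by its label throughout. The labels do not say which exons are flanked by lox sites, so a 3′ tag outside the deleted part would check nothing.

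Few beta-like cells held any Smarcd3 UMI. The share was 1.28% of 2585 cells in the flox/flox library and 2.05% of 2829 in the library labelled BcBKO, at median depths of 38586 and 33007 UMIs. With every cell thinned to 26000 UMIs, which left out 196 and 694 shallower cells, the shares were 0.586% (interval 0.321 to 0.981) and 1.36% (0.912 to 1.95). Macrophage-like cells, a type in which Smarcd3 was taken as absent, had 0 of 415 cells with a UMI (interval up to 0.885%) and 1 of 329 (0.304%), at median depths of 5474 and 5013 UMIs. Endothelial-like cells had 0.547% and 0.578%, at 4396.5 and 4022 UMIs, which the thinned flox/flox share of beta-like cells did not exceed beyond its interval. Thinning took free RNA from beta-like cells but not from endothelial-like cells, so this comparison leans against an excess. Unthinned, a beta-like cell of the flox/flox library held 3.09 times (1.34 to 8.28) as many Smarcd3 UMIs as an endothelial-like or macrophage-like cell. In T/NK-like cells no Smarcd3 UMI was seen, which allows up to 13.4 and 4.50 CPM.

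Beta-like cells made up 35.0% (interval 33.9 to 36.1) of the kept flox/flox cells and 34.1% (33.1 to 35.2) of those labelled BcBKO, a difference of −0.857 percentage points (−2.35 to 0.634). The difference was −2.68 points with doublets kept, −2.42 with each library clustered on its own, −2.28 at a clustering resolution of 2 and −1.99 with the stricter cell filter, each with an interval that excludes 0. Among endocrine-like cells alone they were 78.8% of 3279 and 74.0% of 3822, a difference of −4.82 points (−6.78 to −2.84). Alpha-like cells were 13.0% and 17.3% of the endocrine-like cells, a difference of 4.31 points (2.64 to 5.96), and delta-like cells were 7.29% and 7.56%. Endothelial-like cells were 17.3% of the kept flox/flox cells and 12.5% of those labelled BcBKO, mural-like cells 8.68% and 6.36%, and macrophage-like cells 5.62% and 3.97%. B-like lymphocytes were 0.420% (31 cells) and 2.04% (169 cells), of which a cluster led by Igkc and Jchain, genes of antibody-secreting cells, held 19 and 20 cells and a cluster led by Cd79a and Ms4a1 held 12 and 149. T/NK-like cells were 1.00% and 1.92%, and acinar-like cells, the digestive enzyme cells of the exocrine pancreas, 1.03% and 0.314%.

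The beta-like share of endocrine-like cells differed by −6.15 to −4.51 points under the other settings except at a clustering resolution of 0.5. There no alpha-like or PP-like cluster was named and the difference, among beta-like and delta-like cells alone, was −0.940 points. The whole also differed with no cell filter, where beta-like cells were 85.0% of 3085 and 79.2% of 3655 endocrine-like cells. With each library clustered on its own they were 85.2% of 3035 and 80.7% of 3347. Unnamed clusters held 19.8% and 23.8% of kept cells. Those with several islet hormones held 4.58% and 10.2%, those with few UMIs and no marker among their leading genes 1.21% and 10.97%, and those with markers far below the best cluster 12.5% and 0.941%. The largest clusters of the last 2 groups, with 72 and 866 cells and with 905 and 23 cells, had 1564.5 and 1494 UMIs per cell at the median. They shared Kcnq1ot1 and Meg3 as leading genes and differed by acinar genes such as Cela2a and Pnlip among the leading genes of the latter. Both had insulin genes at 250000 CPM or more, and their best-scoring class was beta in the former and acinar in the latter. Neither is counted in the beta-like shares, and whether they hold beta cells was not tested.

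**Figure D1:**
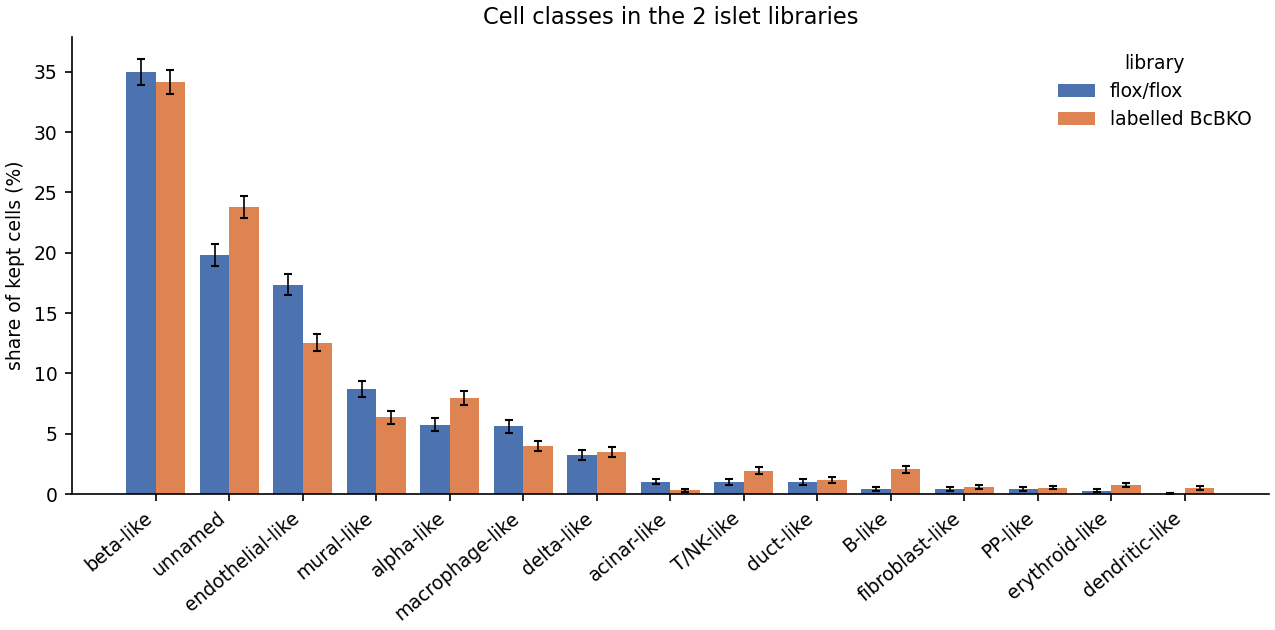
Share of kept cells (%) in each cell class, for the flox/flox library and the library labelled BcBKO, with error bars giving exact binomial 95% intervals of counting error. Beta-like cells stand at 35.0% and 34.1%, while endothelial-like cells stand at 17.3% and 12.5%.

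Within beta-like cells, the precursor gene of the opioid peptide dynorphin, Pdyn, had the highest ratio of the genes eligible to be named, and Rgs2, a regulator of G-protein signalling, had the lowest. Pdyn (ENSMUSG00000027400; chromosome 2, 129686565 to 129699844) went from 36.1 CPM in the flox/flox library to 87.6 CPM in the library labelled BcBKO, a log2 ratio of 1.26 (1.21 to 1.31). Serpina7 (ENSMUSG00000031271; chromosome X, 139079257 to 139085236), which encodes thyroxine-binding globulin, followed at 13.8 and 29.1 CPM (log2 ratio 1.03). Rgs2 (ENSMUSG00000026360; chromosome 1, 143999338 to 144004161) was 318 CPM in the flox/flox library and 148 CPM in the library labelled BcBKO, a log2 ratio of −1.10 (−1.12 to −1.07). The metallothionein genes Mt1 and Mt2, which lie next to each other on chromosome 8 and encode metal-binding proteins, were also lower, from 998.6 to 562 CPM (log2 ratio −0.83) and from 157 to 94.6 CPM (−0.73).

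The 12 highest genes included Tmed6, of a family of secretory cargo proteins, at 16.6 and 28.4 CPM (log2 ratio 0.74). Fkbp11, a proline isomerase of the endoplasmic reticulum, was 106 and 152 CPM (0.51), and Ptprn, a membrane protein of insulin granules known as IA-2, was 74.0 and 103 CPM (0.47). Fh1, the fumarate hydratase of the TCA cycle, was 38.8 and 54.5 CPM (0.48). Also among the 12 highest genes were Dapl1 (115 and 189 CPM, 0.72), Ppat, the first enzyme of purine synthesis (14.9 and 23.7 CPM, 0.63), Spock1, a secreted proteoglycan (16.9 and 25.7 CPM, 0.58), Ccng1, a p53 target gene (19.6 and 29.8 CPM, 0.58), and Zc3h3 (23.5 and 33.3 CPM, 0.49).

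Among the 12 lowest genes, P2ry1, a receptor for ADP, was 46.9 and 34.1 CPM (log2 ratio −0.45), Il6ra, a chain of the interleukin-6 receptor, was 73.8 and 54.7 CPM (−0.42), and Slc2a2, the glucose transporter GLUT2, was 244 and 185 CPM (−0.40). Npas4, a transcription factor induced by depolarisation and calcium, was 62.3 and 44.1 CPM (−0.49), and the antimicrobial peptide gene Defb1 was 174 and 129 CPM (−0.43). Mdm1 (37.9 and 24.6 CPM, −0.60), Noct (24.8 and 16.9 CPM, −0.53), Bpnt1 (43.0 and 30.4 CPM, −0.49) and Mum1l1 (29.8 and 21.4 CPM, −0.46) complete the set.

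Most genes differed little: of 2894 genes with at least 20 CPM in either library, 92.7% had a log2 ratio within 0.25 of 0 and the median was 0.06. The 12 highest and the 12 lowest genes kept their sign under each of the 14 alternative settings run for them. For the other pseudocounts this was fixed in advance. It was so too for TMM scaling and totals without hormones and mitochondrial genes, which moved the median of all genes by only −0.07 and −0.06. The other settings drew on largely the same cells, so the kept signs are no independent support. Pdyn, Serpina7, Dapl1 and Fkbp11 were leading genes of a beta-like cluster with 41 cells of the flox/flox library and 334 of the library labelled BcBKO, and without it, a setting chosen after seeing the data, their log2 ratios were 1.20, 0.87, 0.66 and 0.47. RNA of acinar cells, summed over their marker genes, was 227 CPM in beta-like cells of the flox/flox library and 37.8 CPM in those labelled BcBKO.

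**Figure D2:**
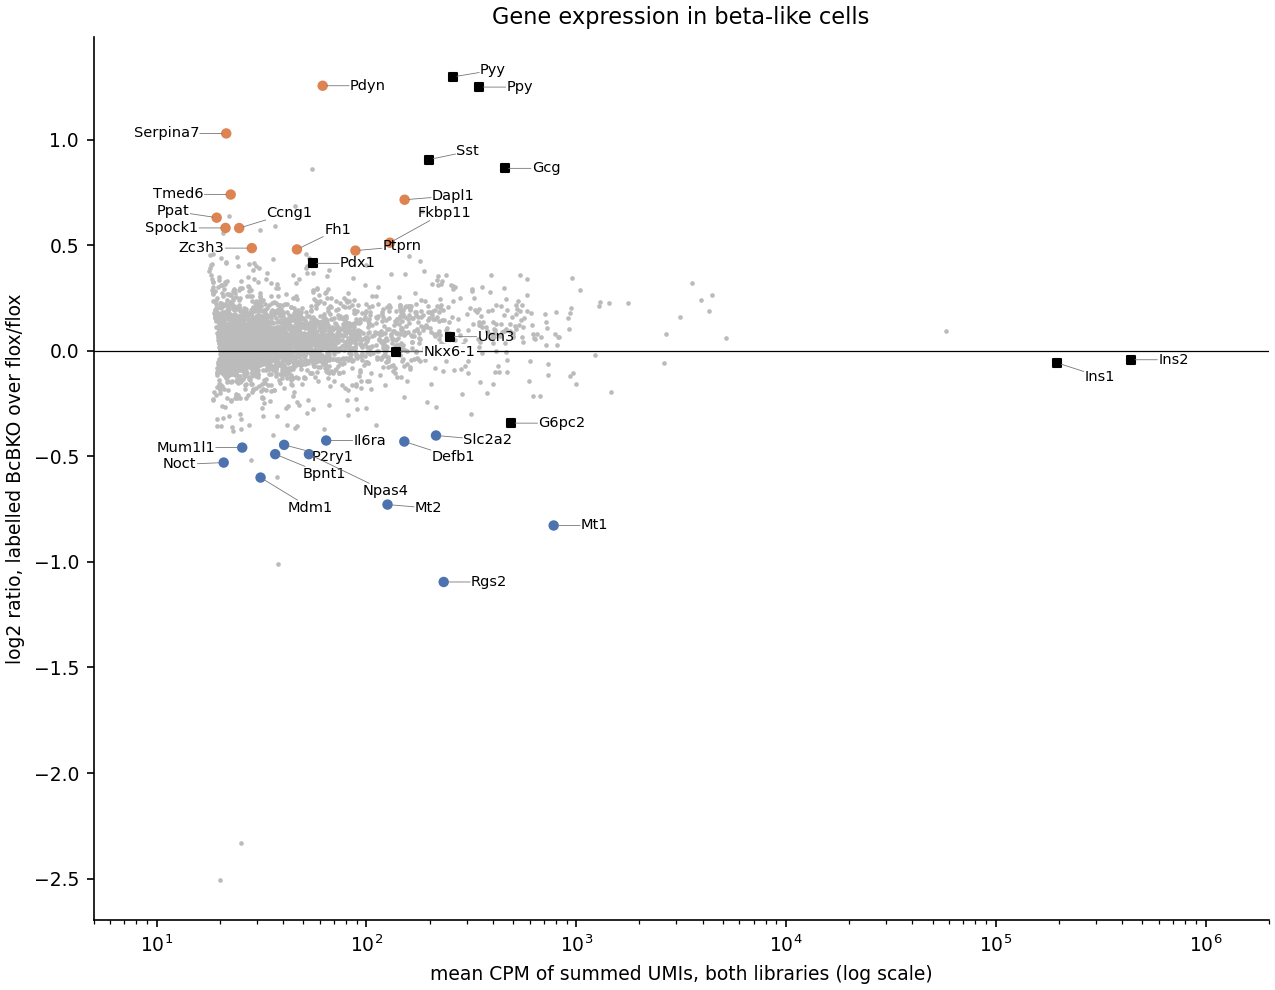
Log2 ratio of the library labelled BcBKO over the flox/flox library against mean CPM (log scale) for genes with at least 20 CPM in beta-like cells, with no error bars; orange and blue points are named genes among the 12 highest and the 12 lowest, black squares are hormone and beta-cell identity genes, and grey points are all other genes. Pdyn at 1.26 and Rgs2 at −1.10 lie furthest out among the orange and blue points, Ins1 at −0.06 and Ins2 at −0.04 lie near 0, and the lowest grey points include the acinar genes Prss2 at −2.51 and Ctrb1 at −2.33.

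Genes of beta-cell identity did not move in a common direction. Of the 23 members at 20 CPM or more, 12 had a log2 ratio above 0 and 11 below, with a median of 0.05 (−0.01 to 0.07), at percentile 13.4 of 10000 random lists of genes with matched levels. The insulin genes Ins1 and Ins2 had log2 ratios of −0.06 and −0.04, Nkx6-1 was 139 CPM in both libraries, and Ucn3, a peptide gene of mature beta cells, had a ratio of 0.07. The transcription factors Pdx1 (47.4 and 63.5 CPM, 0.41) and Nkx2-2 (43.1 and 59.7 CPM, 0.46) were higher in the library labelled BcBKO, and G6pc2, an islet glucose-6-phosphatase (547 and 431 CPM, −0.34), was lower with Slc2a2. Mafa, a transcription factor of mature beta cells, was under the minimum at 0.75 and 1.30 CPM. The list median turned to −0.02 with TMM scaling, −0.01 with totals without hormones and mitochondrial genes and −0.02 with thinned cells.

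Hormones of the other islet cells were higher in beta-like cells of the library labelled BcBKO. Gcg (glucagon) was 322 and 588 CPM (log2 ratio 0.86), Sst (somatostatin) 138 and 260 CPM (0.91), Ppy (pancreatic polypeptide) 204 and 486 CPM (1.25) and Pyy (peptide YY) 149 and 367 CPM (1.30). The list median was 1.08 (1.06 to 1.10), at percentile 100. By mean UMIs per cell the log2 ratios were 0.65, 0.69, 1.03 and 1.08, and without the 10% of cells with the most UMIs of each hormone they were 0.49, 0.68, 0.39 and 0.64. The same transcripts were also higher in cells that do not make them: in endothelial-like cells Gcg was 1447 and 1854 CPM (0.36), Sst 242 and 662 CPM (1.45), and Ppy 373 and 648 CPM (0.80), with log2 ratios of mean UMIs per cell of 0.17, 1.27 and 0.61. The dedifferentiation and progenitor list had 4 of its 16 genes at 20 CPM or more. Of these, Serpina7, Cd81 (0.30) and Gc (0.28) were higher and Sox4, a transcription factor of endocrine progenitors, was lower (−0.31). Their median was 0.29, at percentile 99.9. Aldh1a3, an enzyme used as a marker of dedifferentiated beta cells, was under the minimum at 13.2 and 17.4 CPM.

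Mitochondrial genes were slightly higher in the library labelled BcBKO. Of 12 genes encoded by mitochondrial DNA, 10 had log2 ratios above 0, with a median of 0.23 (0.23 to 0.24) at percentile 100; mt-Nd1 was at 0.35 and mt-Co3 at 0.32, while mt-Nd4l was at −0.21 and mt-Atp8 at −0.04. Of 44 nuclear genes of oxidative phosphorylation, 42 were above 0, with a median of 0.12 (0.10 to 0.14) at percentile 99.4; Atp5o of the ATP synthase was at 0.35, and Uqcrc2 was lowest at −0.06. With TMM scaling 46.1% of all 2894 genes were above 0, against 70.1% with total UMIs, and the medians of both lists stayed above 0 under every setting, at 0.05 for the nuclear genes with TMM scaling. The mitochondrial pattern was also seen in cells that are not endocrine: mt-Nd1 and mt-Co3 were at 0.35 and 0.37 in endothelial-like cells and 0.21 and 0.26 in mural-like cells, and mt-Nd4l was at −0.36 and −0.42.

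Granule and exocytosis genes had a median of 0.11 (0.10 to 0.14) at percentile 94.1, with 18 of 24 above 0, and 0.04 with TMM scaling. Pam, which amidates peptide hormones, was 154 and 208 CPM (0.43), while Slc30a8, the zinc transporter of insulin granules, was 403 and 351 CPM (−0.20). Among 7 genes of sterol and fatty acid synthesis, the desaturase gene Scd2 was highest (15.4 and 20.5 CPM, 0.39), and Fdps, an enzyme of isoprenoid synthesis, was at −0.06. The list median was 0.16, at percentile 97.7, and 0.02 with totals without hormones and mitochondrial genes.

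Stimulus-secretion coupling genes had a median of −0.05 (−0.10 to −0.01) at percentile 0.36, with 5 of 10 above 0: Slc2a2 and the cation channel gene Trpm5 (−0.23) were lowest, and the calcium pump gene Atp2a3 (0.18) and the calcium channel gene Cacna1a (0.15) were highest. This median turned above 0 under 3 settings, with the stricter cell filter, with doublets kept and without the minimum level for genes.

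Immediate-early genes, which dissociation of tissue can induce, were lower as a group. Of 20 members, 15 had log2 ratios below 0, with a median of −0.08 (−0.10 to −0.07) at percentile 0, and the median stayed below 0 under every setting, at −0.15 with TMM scaling. Npas4 and Atf3 (−0.30) were lowest, while Egr1 (0.13) and Dusp1 (0.11) were above 0. The same list was below 0 in endothelial-like cells (median −0.20) and in mural-like cells (−0.22).

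The remaining lists lay inside the central 95% of random matched lists. For incretin and cAMP signalling the median was 0.09 (percentile 74.3), with the phosphodiesterase gene Pde10a at 0.58, Gipr, the GIP receptor, at −0.20, and Glp1r, the GLP-1 receptor, under the minimum at 2.38 and 2.39 CPM. BAF and PBAF subunits had a median of 0.11 (percentile 88.5), with Smarcc2 at 0.15 and Smarca2 at 0.13. The p53 and apoptosis list was at 0.11 (percentile 89.0; Cdkn1a, the inhibitor p21, 0.32), interferon and antigen presentation at 0.10 (81.5; Ifi27 0.34, B2m 0.30) and oxidative stress defence at 0.09 (80.7; Sod1 0.36, against Mt1 and Mt2). Medians that crossed 0 under at least 1 scaling were those of the TCA cycle list (0.04, percentile 39.9), ER stress and protein folding (0.06, 27.8; Ssr4 0.34, Ppp1r15a −0.22), glycolysis (0.01, 11.2; Gapdh 0.24), proliferation (0.06, 43.1), the sex-linked list and hypoxia response (0.06, 52.1; Bnip3 −0.19). None of the 23 genes disallowed in beta cells reached 20 CPM. Of the sex-linked genes, Ddx3y was at 0.17 and Eif2s3y at −0.08 (median 0.04, percentile 42.1), and over all kept cells Xist was at 0.0752 and 0.112 CPM.

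**Figure D3:**
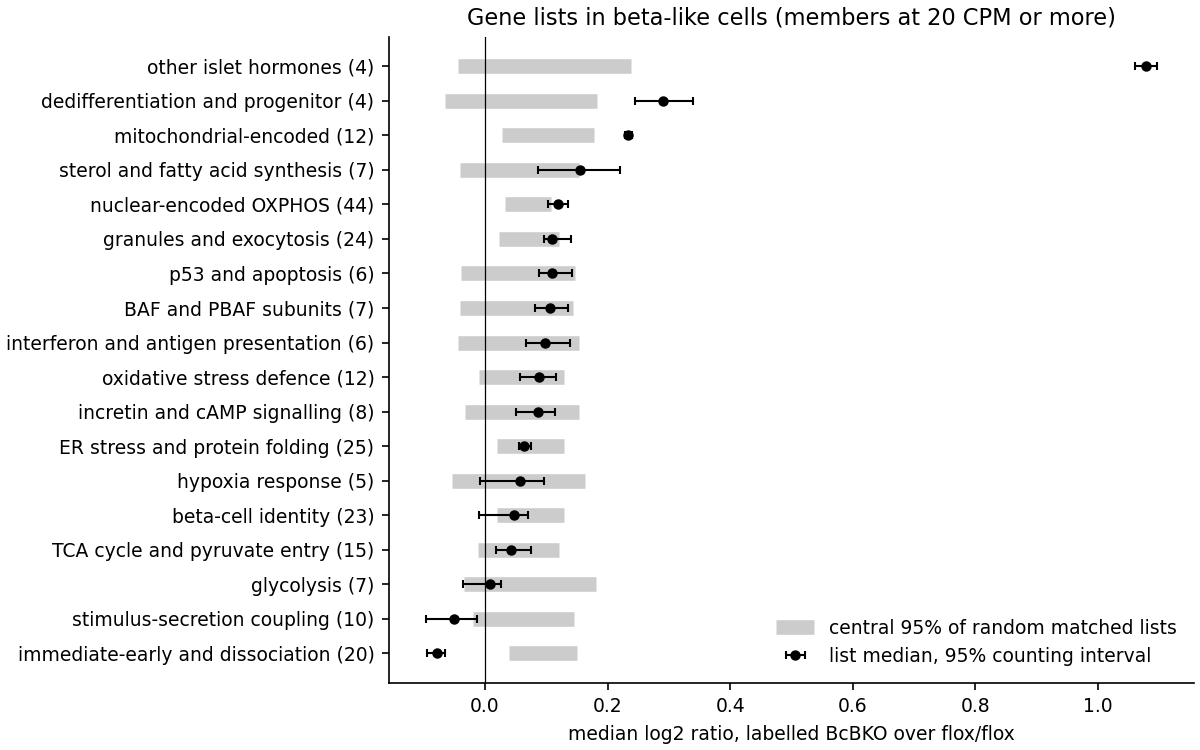
Median log2 ratio of the library labelled BcBKO over the flox/flox library for each gene list in beta-like cells (black points, bars giving 95% counting intervals) over the central 95% of random lists with matched levels (grey bars), with the number of members in parentheses. Other islet hormones lie furthest to the right at 1.08, and the immediate-early list at −0.08 lies left of its random lists.

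In alpha-like cells, the glucagon cells of the islet, Nr4a2, an early-response nuclear receptor, was the highest of 1632 genes eligible to be named, at 37.5 CPM in the flox/flox library and 64.2 CPM in the library labelled BcBKO (log2 ratio 0.76, 0.55 to 0.98). It was followed by the oxytocin receptor gene Oxtr (0.57), the histone demethylase gene Kdm7a (0.56), Tmed8 (0.56) and the vitamin D receptor gene Vdr (0.54). Basp1 was lowest, at 152 and 85.7 CPM (−0.82), ahead of Fkbp5, a glucocorticoid-induced chaperone gene (−0.69), the secreted signal gene Wnt4 (239 and 169 CPM, −0.50) and Por (−0.44). All 10 genes of the beta-cell identity list at 50 CPM or more were above 0 in alpha-like cells, with a median of 0.33 at percentile 100. Of all 1879 genes at that level, 1375 were above 0 too. Several of the 10 are not particular to beta cells. In the flox/flox library Isl1 was 212 CPM in alpha-like and 95.7 CPM in beta-like cells, and Neurod1 was 146 and 81.1 CPM. Pax6, Nkx2-2, Foxa2 and Slc30a8 were also higher in alpha-like cells there, while Ins1, Ins2, Iapp and Ero1lb were lower. The 10 genes include Ins2, at 17234 and 23362 CPM (0.44), but by mean UMIs per cell its log2 ratio was 0.12 in alpha-like cells. The median alpha-like cell held 181 and 192.5 Ins2 UMIs, beside 155 and 156 in endothelial-like cells, which do not make insulin. The other islet hormones had a median of −0.41, and Sst was 1995 and 463 CPM (−2.10), a ratio carried by a minority of cells: the median alpha-like cell held 1 and 2 Sst UMIs, and 68.0% and 85.2% of cells held any. Granule genes had a median of 0.16 (percentile 99.6), mitochondrial genes 0.17 (percentile 100) and immediate-early genes 0.02 (percentile 4.44), beside a median of 0.08 over all genes.

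In delta-like cells, the somatostatin cells, all 20 immediate-early genes at 50 CPM or more were lower in the library labelled BcBKO. Their median was −0.29 (−0.34 to −0.25), at percentile 0. Gadd45b, a stress-induced gene, was 135 and 64.3 CPM (log2 ratio −1.06), and Ppp1r17, a phosphatase inhibitor gene, was lowest at 156 and 72.9 CPM (−1.09). Defb1 (173 and 86.3 CPM, −0.99), Arid5b (−0.85) and Mdm1 (−0.84) followed. The highest genes were Fam193a (0.66), Tox3 (0.63), Akirin1 (0.61), Nop56 (0.60) and Kctd12 (0.59), each resting on at most 317 UMIs per library. The median over all 2711 genes was −0.03, nuclear genes of oxidative phosphorylation were at −0.03 (percentile 49.5) and mitochondrial genes at 0.07 (percentile 99.5).

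Part of the difference between the libraries was shared by cell classes other than beta-like cells. The acinar enzyme genes Prss2 and Ctrb1, which none of the other classes makes, were lower in the library labelled BcBKO in all 8 classes compared, with log2 ratios from −3.32 (Ctrb1 in T/NK-like cells) to −1.78 (Ctrb1 in duct-like cells). Mt1 was lower in all 8 classes as well, at −0.89 in endothelial-like, −0.92 in mural-like, −0.64 in delta-like, −0.40 in alpha-like and −0.28 in macrophage-like cells, beside −0.83 in beta-like cells. Mt2 was lower in 6 of them but was 0.07 in alpha-like cells (−0.12 to 0.27) and 0.41 in T/NK-like cells (−0.95 to 2.51). Rgs2 was lower in delta-like (−0.58), endothelial-like (−0.39) and mural-like cells (−0.48), but was at 0.05 in alpha-like and 0.19 in macrophage-like cells. Of the 12 highest genes of beta-like cells, 12 were above 0 in alpha-like and in macrophage-like cells. In endothelial-like cells 10 were above 0, in mural-like cells 8 and in delta-like cells 5. Pdyn was 4.29 and 12.4 CPM in endothelial-like cells (1.34), but was at −0.02 in delta-like cells. Free RNA of beta cells was not removed and could give part of these values. Mt1 was 998.6 and 562 CPM in beta-like cells, beside 92.0 and 49.1 CPM in endothelial-like and 119 and 62.3 CPM in mural-like cells. In macrophage-like cells it was 1162 and 959 CPM. Rgs2 was 318 and 148 CPM in beta-like cells, beside 52.2 and 37.1 CPM in mural-like cells. Mdm1 and Il6ra had higher CPM in alpha-like and delta-like cells than in beta-like cells of both libraries, and were lower there as well. In alpha-like and delta-like cells Mdm1 was at −0.81 and −0.84, and Il6ra at −0.29 and −0.60.

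Across genes, the log2 ratios of beta-like cells correlated with those of delta-like cells at Pearson r = 0.54, of endothelial-like cells at 0.45, of mural-like cells at 0.40, of alpha-like cells at 0.35 and of macrophage-like cells at 0.30, with acinar, hormone and mitochondrial genes left out (783 to 990 genes). With those genes kept, the values were 0.53, 0.54, 0.52, 0.17 and 0.42 in the same order. RNA of beta cells in other droplets was not removed for either, and genes are not independent replicates.

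**Figure D4:**
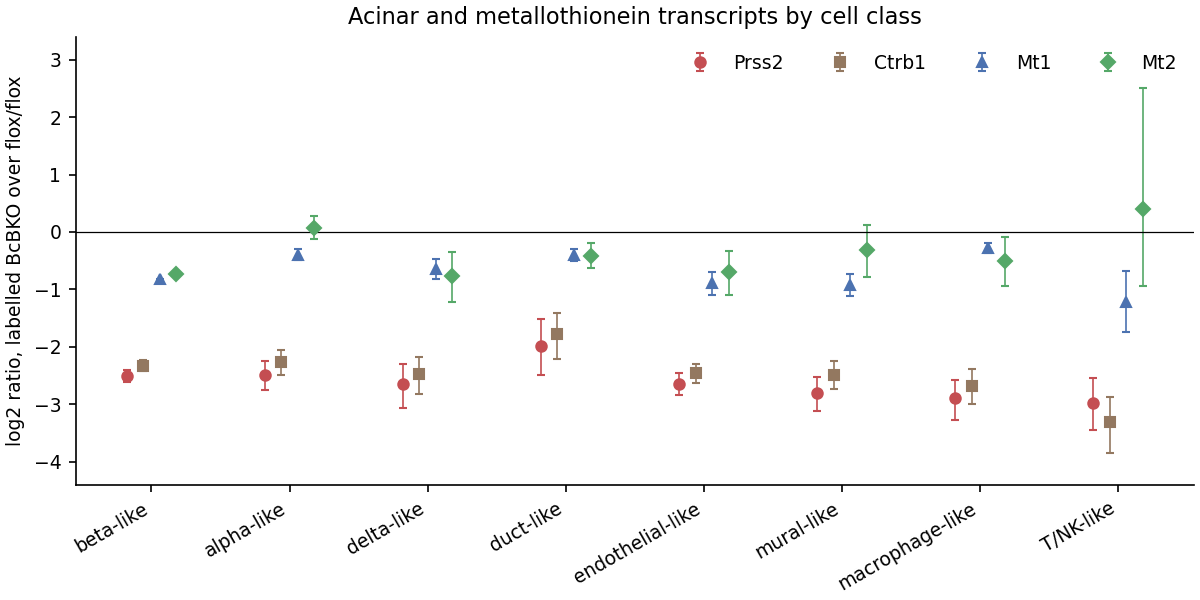
Log2 ratio of the library labelled BcBKO over the flox/flox library for the acinar genes Prss2 and Ctrb1 and the metallothionein genes Mt1 and Mt2 in 8 cell classes, with bars giving 95% counting intervals. Prss2, Ctrb1 and Mt1 lie below 0 in every class, and Mt2 is above 0 in alpha-like cells at 0.07 and in T/NK-like cells at 0.41.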

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

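All tests in this part were chosen only after the results were seen, and the differences between cell classes in the first paragraph were not tested.

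A gene was singled out where its log2 ratio in alpha-like or delta-like cells had the opposite sign to that in beta-like cells, with both intervals more than 0.1 from 0, at 50 CPM or more in that class, unless its CPM was over 5 times higher in beta-like cells. The hormone genes Sst (−2.10), Ppy (−0.47) and Pyy (−0.35) were lower in alpha-like cells, against 0.91, 1.25 and 1.30 in beta-like cells. For Sst a minority of cells carries this, since the median alpha-like cell held 1 and 2 UMIs and 68.0% and 85.2% of cells held any. Gc, the vitamin D-binding protein gene, was −0.35 in delta-like cells against 0.28 in beta-like cells. Slc30a8 was 0.20 in alpha-like cells against −0.20 in beta-like cells. Egr1 was −0.28 in delta-like cells against 0.13 in beta-like cells. Cdkn1a was −0.81 in delta-like cells against 0.32 in beta-like cells.

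Smarcd3 was not lower in beta-like cells of the library labelled BcBKO. Free RNA is argued against as the source of its UMIs, since a beta-like cell of that library held 4.01 times (1.83 to 10.4) as many as an endothelial-like or macrophage-like cell. It held 1.91 times (1.20 to 3.104) the sum of free RNA and of what attached cells or missed doublets would bring, estimated from the median share of each named type's markers in beta-like cells. Loss of the counted tag from nearly all beta cells, with the labels right, would leave only these sources, which that value argues against for the types counted. Its interval leaves out error in the marker shares, and unnamed clusters were not counted as sources. Loss from fewer cells is not excluded by the ratio of CPM, 1.87 (1.20 to 2.96), because the flox/flox UMIs may themselves come from such sources. What stays open is a tag outside the deleted part, loss of the tag from part of the beta cells, recombination in few cells, and swapped labels. With the tag lost from nearly all beta cells of the flox/flox library, its UMIs would be those of the same other sources. They were 1.45 times (0.862 to 2.43) these, while partial loss was not tested. Of the 0.0047 UMIs per beta-like cell put down to other named types there, 0.003621 came from the 73 duct-like cells, a cluster whose name is uncertain. In the library labelled BcBKO, 0.003504 of 0.0056 UMIs came from its 95 duct-like cells.

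Gcg, Sst, Ppy and Pyy were higher in beta-like cells of the library labelled BcBKO. Free RNA in every droplet may account for part: without the top 10% of cells, the median log2 ratio of mean UMIs was 0.34 in endothelial-like, mural-like and macrophage-like cells and 0.56 in beta-like cells. A minority of beta-like cells carrying RNA of another endocrine cell was not decided for any hormone by the bounds set for the part kept. That part is the log2 ratio without the top 10% of cells over the one with all cells. Ppy was 0.39 against 1.03 (part kept 0.38, 0.23 to 1.04) and Pyy 0.64 against 1.08 (0.59, 0.43 to 1.00). Sst was 0.68 against 0.69, with a very wide interval (0.99, −5.57 to 9.15). Gcg was 0.49 against 0.65, and most of its ratio was kept (0.75, 0.62 to 0.95). Clusters with several hormones, which doublets or attached cells could form, were also a larger part of that library. An effect of the genotype on hormone genes stays open and was not tested, because genotype and library are the same split.

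Rgs2, Mt1, Mt2, Npas4 and others of the 12 lowest genes of beta-like cells may reflect a difference in handling of the islets. Such a difference would reach cells of every type, and relative to all genes the immediate-early list was −0.26 in delta-like, −0.22 in mural-like and −0.20 in endothelial-like cells, but −0.0651 in alpha-like and −0.0538 in macrophage-like cells, which leaves it undecided. Of the 12 genes themselves, 11 were below 0 in delta-like and in mural-like cells, 10 in endothelial-like, 9 in macrophage-like and 6 in alpha-like cells. RNA of beta cells was not removed there. The 12 highest genes were likewise mostly above 0 in these classes, except in delta-like cells. Npas4 was at −1.57 in macrophage-like, −0.80 in mural-like, −0.31 in delta-like and −0.29 in endothelial-like cells but 0.24 in alpha-like cells. Its levels were low in macrophage-like (13.6 and 3.91 CPM), mural-like (6.05 and 3.04 CPM) and endothelial-like cells (9.70 and 7.76 CPM). Only 31 of 415 and 7 of 329 macrophage-like cells held any of its UMIs. Rgs2 was at 0.05 in alpha-like and 0.19 in macrophage-like cells. The genotype stays open and was not tested. It could act in beta cells, through them on other cells, or in other pancreatic cells where the Pdx1 promoter had been active.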

How the results depend on the processing

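The alternative without the beta-like cluster mostly of 1 library was chosen after seeing the data; all others were planned. No paired analysis was possible because each group has 1 library. Each of the 12 highest and the 12 lowest genes of beta-like cells kept its sign under the 14 alternatives run for it, with Pdyn from 1.17 to 1.37 and Rgs2 from −1.16 to −1.07. The changes of pseudocount and of scaling among them could not have turned genes chosen this far from 0. The other alternatives drew on largely the same cells and were not independent checks. Of the main results under each alternative, 31 stayed within the counting interval and 11 moved outside it; the identity list median, whose interval includes 0, changed sign under 4 alternatives. For named genes the counts were 1109 and 272 with 5 reversed, and for lists other than identity 211 and 83 with 8 reversed. Values whose interval includes 0 are not counted as reversed: among them the sign changed in 41 cases for named genes and in 9 for these lists, all of the glycolysis, hypoxia response and sex-linked lists. The causes were not tested unless stated.

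The beta-like share of endocrine-like cells differed by −0.940 points at Leiden resolution 0.5, against −4.82, because no alpha-like or PP-like cluster was named there and the whole is another. The beta-like share of kept cells differed by −2.68 points with doublets kept and −2.42 with each library clustered on its own, against −0.857. Smarcd3 was at a log2 ratio of 0.49 with totals without hormones and mitochondrial genes, 0.72 with a pseudocount of 0.1 CPM and 0.0674 with 5 CPM, against 0.26; these follow from the size of the pseudocount beside its level. The identity list median was 0.0707 with no cell filter, −0.0173 with TMM scaling, −0.0137 with totals without hormones and mitochondrial genes, −0.0153 with cells thinned, −0.0036 at 100 CPM or more, where it stayed within its interval, and 0.0721 without the beta-like cluster mostly of 1 library. TMM scaling moved the median of all genes by −0.07, and totals without hormones and mitochondrial genes by −0.06.

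Reversals were of values near 0. The stimulus-secretion list was 0.0118 with the strict cell filter, 0.009 with doublets kept and 0.036 with no filter on low genes. With TMM scaling Ccnd2 was −0.0034, Ccnd1 −0.0047, the TCA cycle list −0.0247, the ER stress and protein folding list −0.0039 and the proliferation list −0.004. With totals without hormones and mitochondrial genes Ccnd1 and the proliferation list were −0.0006. With equal weight per cell mt-Atp8 was 0.0006 and Eif2s3y 0.0014. At 100 CPM or more the oxidative stress list was −0.0, and the dedifferentiation and sex-linked lists had no members left and no value. The cause was not tested. Smarcd3, Mafa and Glp1r were each under 3 CPM in beta-like cells.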

Other observations

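The genes and tests of this part were chosen only after the data were seen.

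Some neuropeptide genes under the minimum level were higher in beta-like cells of the library labelled BcBKO. Cck, the cholecystokinin gene, was 0.282 and 3.48 CPM, Npy, the neuropeptide Y gene, was 0.159 and 2.97 CPM, and Vgf, a granule peptide precursor gene, was 6.90 and 12.5 CPM. The p53 target gene Phlda3 was 1.82 and 5.47 CPM. Cck and Npy were leading genes of the beta-like cluster that came mostly from 1 library (41 and 334 cells). Without it, Cck was 0.288 and 2.96 CPM, Npy 0.162 and 1.07 CPM, Vgf 6.92 and 12.01 CPM and Phlda3 1.801 and 4.97 CPM, while Pdyn was at a log2 ratio of 1.20 and Serpina7 at 0.87.

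Fkbp5, a glucocorticoid-induced chaperone gene, was lower in the library labelled BcBKO in each of 6 classes, at a log2 ratio of −1.34 in endothelial-like cells (142 and 55.3 CPM), −1.60 in mural-like, −1.998 in macrophage-like, −1.05 in delta-like, −0.69 in alpha-like and −0.56 in beta-like cells. Zbtb16, another glucocorticoid-induced gene, was −2.17 in mural-like cells. Per1 (−0.56) and Klf9 (−0.46) were lower in endothelial-like cells.

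A hypothesis is that islets of the library labelled BcBKO had seen less glucocorticoid signalling, which may also account for part of the lower Mt1 and Mt2. Tested on a list of glucocorticoid-induced genes without Fkbp5, Mt1 and Mt2, the list median was −0.34 in endothelial-like cells (5 genes, percentile 0.04 of random matched lists) and −0.20 in mural-like cells (7 genes, percentile 0.52). Zbtb16, Per1 and Klf9 are members of this list, so the test is not independent of their values given above. In macrophage-like cells the list median was at percentile 54.8 (5 genes). It was at 1.52 in beta-like, 1.90 in delta-like and 4.46 in alpha-like cells (3 genes each). Arrdc3 went the other way, at 0.62 in endothelial-like and 0.53 in mural-like cells. Sgk1 was at −0.06 in endothelial-like cells (888 and 851 CPM) but at 0.22 in mural-like and 0.38 in macrophage-like cells. Errfi1 was at 0.30 in beta-like cells. Handling, time of day and stress of the animals were not recorded in the labels, so the source of such a difference was not tested.

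A strain-derived segment around a floxed allele would make neighbours of Smarcd3 differ more than other genes. The 29 genes within 10 Mb of Smarcd3 had a median absolute deviation at percentile 84.6 of random matched lists, above their middle but inside the central 95%, which decides neither way.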
